A study of Homo sapiens with 6 samples.

How the data were processed

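The 6 libraries analysed were from RNA sequencing of bone marrow human mesenchymal stem cells, 3 libraries from culture at 20% O2 and 3 from culture at 2% O2. Per the labels, total RNA was extracted with Trizol and treated with DNase I, and poly(A) RNA was made into libraries with a kit that does not mark strand. A seeding density is stated for the hypoxia culture alone. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the 3 replicates came from separate donors, cultures or passages, so p-values measure only the spread between these samples, which may be technical.

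The authors deposited a table of raw read counts per gene symbol, with whole numbers and no normalization. The build is hg38 per the submitters' processing notes. The aligner, the counting program and its annotation are not given in the sources used here. The deposited table of the authors' own comparison holds a log2 fold change of hypoxia over 2D with its standard error per the file headers. It also holds a mean normalized signal per gene, a test score equal to the fold change over its standard error, and a p-value with its adjusted p-value, per the file headers. The program behind it is not given in the sources used here, though some of its column names are those that DESeq2 writes and others those of limma. All 6 columns of counts matched a sample title.

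The count table lists 27971 gene symbols, 7258 of them without counts. Total counts were 44201042, 16216220 and 34971728 in 2D replicates 1 to 3 and 28929115, 30522609 and 16523242 in hypoxia replicates 1 to 3. Entries that name no gene stayed out of library sizes and tests. Reads in no gene were 3.40%, 5.08% and 2.80% of the totals in 2D and 8.32%, 7.65% and 8.60% in hypoxia, and reads shared by more than 1 gene averaged 3.02% in 2D and 2.81% in hypoxia. The 95% intervals (Wilson) of the shares in no gene were at most 0.0270 percentage points wide. Such intervals cover counting error only. No pair of libraries differed by as little as sampling noise, the closest being hypoxia replicates 1 and 3 with a chi-square per degree of freedom of 5.28. The other pairs within a culture had 46.3 to 308, though this value also depends on depth. Hypoxia replicates 1 and 3 may thus be closer than separate cultures would be, and n = 3 may overstate the independent samples of hypoxia. Transcript GC content, length and coordinates came from GENCODE release 29 on the same build, to which 92.3% of symbols were matched, directly or through older symbols. For 97.6% of the tested genes a GC content and length were found. Reads of near-identical copies cannot be told apart here, which makes the values of ribosomal protein, histone and metallothionein genes and of genes with processed pseudogenes such as AK4 and BNIP3 uncertain, and without strand a gene cannot be separated from an antisense partner.

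The main test was edgeR 4.0.16 (R 4.3.3) with filterByExpr, TMM factors, robust quasi-likelihood fits of all 6 libraries on culture, and Benjamini-Hochberg adjustment with a threshold of 0.05. Standard errors were the log2 fold change over the square root of the F statistic. Log2 expression used a prior count of 2. CPM values are TMM-normalised. The 32 gene lists were fixed before the data were examined, as were the samples, tests and the other settings named below. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, then with an estimated correlation and with fry. The list of mitochondrially encoded mRNAs, with 0 members in the count table as used here, was left out. P-values of the 31 lists were adjusted together. In each list the p-values of the members were also adjusted over the list alone. Genes named in the text followed a rule fixed in advance: up to 12 genes per direction with the largest change among called genes with a mean of at least 5 CPM and no overlap of the groups, the 3 members with the smallest p of each list of pathways or identity genes, the most abundant member and the one with the smallest p of each list of other cell types or RNA classes, and 19 genes of oxygen sensing, EVs and hMSC identity named beforehand. Genes of the Y chromosome and XIST were not reported.

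The other settings fixed then were DESeq2 1.42.0, limma-voom, DESeq2 size factors, upper-quartile factors or library totals in edgeR, no filter, a filter of 1 CPM in every library of a group, the replicate number as a block, leaving out each library, a log2 fold change of at least 1, a test against a 1.2-fold change and an adjusted p under 0.01. After the data were seen 4 were added: offsets from natural splines (4 degrees of freedom each) of GC content and log2 length, fitted per library to genes of at least 1 CPM, 1 surrogate variable (sva 3.50.0), 2D replicate 2 as the only 2D library, which assumes that a lone 2D library would vary like the hypoxia libraries, and the replicate block with the GC and length offsets. Upper-quartile factors moved the median log2 fold change of all genes from -0.02 to 0.08.

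The tests were tried on simulated counts for hypoxia against 2D. With the dispersion estimated from the 6 libraries, edgeR called 72% of genes changed 4-fold and 5% of those changed 2-fold among 13732 genes, with 6.10% of its calls false. At a dispersion of 0.02 it called 100% of both among 13802 genes. With a GC trend added to each library at that dispersion it called 0% of either among 13784 genes, and 100% of both after the GC and length correction, with 9.09% of the calls false. The added trend was linear in GC content, a form the correction can remove, and held no length trend. The corrected real libraries had a larger dispersion (its square root, the biological coefficient of variation, was 0.253). This recovery therefore need not hold for them. Camera gave an adjusted p of 5.97e-27 to a list of 30 genes raised 2-fold and called 0 of 50 unchanged lists, in simulations without correlation between genes. Figures were drawn with matplotlib 3.10.9.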

Results

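Gene expression was measured by sequencing poly(A)-selected RNA of bone marrow human mesenchymal stem cells (hMSCs), fibroblast-like stromal cells of the marrow that can be driven to form bone, fat or cartilage. The 6 libraries were 3 of cells grown in a standard incubator at 20% O2, called 2D here after the labels, and 3 of cells grown at 2% O2 in an oxygen-controlled chamber, called hypoxia. Both were monolayer cultures. The series concerns the extracellular vesicles (EVs), small membrane particles shed by cells, that hMSCs release in hypoxia. The RNA was that of the cells, so the comparison asks how their transcripts differed at low oxygen, including those of the machinery that makes vesicles. Effects of oxygen cannot be told apart from those of anything else that differed between the groups. Seeding density, for example, is stated for the hypoxia culture alone. Counts assigned to genes came to 41366082, 14910320 and 32915468 in 2D replicates 1 to 3 and to 25728391, 27291599 and 14644857 in hypoxia replicates 1 to 3. After a filter on low counts 13918 genes were tested.

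The libraries did not separate by culture alone. The first principal component of log2 expression held 67.8% of the variance and placed 2D replicate 2 at 33.2, beside the hypoxia libraries at 52.8, 36 and 52.6, while 2D replicates 1 and 3 lay at -77.4 and -97.2. Measured over all tested genes on a line from the mean of 2D replicates 1 and 3 (position 0) to the hypoxia mean (position 1), 2D replicate 2 had a position of 0.840 (95% bootstrap interval over genes 0.830 to 0.851). Spread in the mean of 2D replicates 1 and 3 enters both differences behind this position and raises it above 0 even without likeness. The division of the libraries followed the base composition of the transcripts. In the quartile of genes with the highest GC content the median log2 difference of hypoxia from 2D was -1.06, against 0.33 in the quartile with the lowest, and across genes Spearman's rho between GC content and log2 fold change was -0.641 (genes are not independent replicates). The difference of 2D replicate 2 from 2D replicates 1 and 3 had a rho of -0.797 with GC content. The spread of 2D that enters every test below therefore includes this difference, and the biological coefficient of variation was 0.353 with all libraries and 0.236 without 2D replicate 2.

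**Figure D1:**
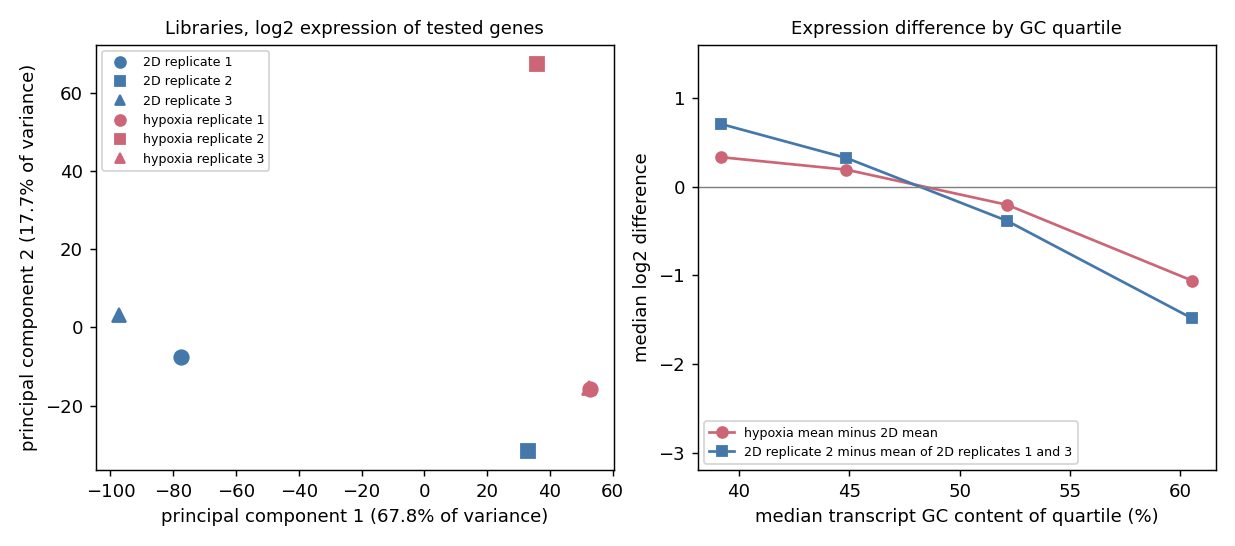
Left, the 6 libraries on the first 2 principal components of log2 expression of the tested genes (horizontal and vertical axes, with the percentage of variance of each), with color for culture and marker shape for replicate. Right, median log2 expression difference (vertical axis) in the 4 quartiles of transcript GC content (horizontal axis, percent), for hypoxia against 2D and for 2D replicate 2 against 2D replicates 1 and 3. 2D replicate 2 lies at 33.2 on the first component, on the side of the hypoxia libraries, and hypoxia against 2D goes from 0.33 in the lowest quartile to -1.06 in the highest.

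In hypoxia, hMSCs carried 4.70 to 6.17 times as much RNA of 5 genes and 0.167 times as much of FOS. P4HA1, the catalytic subunit of the prolyl hydroxylase that matures collagen, rose from 108 ± 16.7 CPM (counts scaled by library size and TMM factor) in 2D to 669 ± 82.5 in hypoxia (mean ± SD, n = 3 each). BNIP3, a mitochondrial outer membrane protein that acts in mitophagy, rose from 85.3 ± 12.3 to 412 ± 66.6 CPM, and AK4, a mitochondrial adenylate kinase, from 17.0 ± 1.48 to 79.8 ± 13.7 CPM. MXRA5, a matrix-associated protein, rose from 21.9 ± 3.90 to 103 ± 2.31 CPM, and MEG3, an imprinted long noncoding RNA, from 32.7 ± 5.47 to 154 ± 12.03 CPM. FOS, a subunit of the AP-1 transcription factor that responds within minutes to growth factors and stress, fell from 262 ± 34.3 to 43.6 ± 0.878 CPM.

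These were the 6 genes past an adjusted p of 0.05 in edgeR's quasi-likelihood test. The log2 fold changes were 2.62 ± 0.21 (SE) for P4HA1 (adjusted p = 0.0316), 2.27 ± 0.22 for BNIP3, 2.24 ± 0.20 for MXRA5, 2.23 ± 0.20 for MEG3 and 2.23 ± 0.21 for AK4 (adjusted p = 0.0339 for each of the last 4), and -2.59 ± 0.19 for FOS (adjusted p = 0.0312). At an unadjusted p under 0.05, 1441 genes were higher and 2730 lower. The libraries of the 2 cultures did not overlap for any of the 6. In GENCODE 29 on the hg38 build P4HA1 spans chromosome 10 from 73007217 to 73096974 on the minus strand and BNIP3 chromosome 10 from 131966455 to 131982013 on the minus strand. AK4 lies on chromosome 1 from 65147549 to 65232145 (plus strand), MXRA5 on chromosome X from 3308565 to 3346641 (minus strand), MEG3 on chromosome 14 from 100779410 to 100861031 (plus strand) and FOS on chromosome 14 from 75278774 to 75282230 (plus strand). All counts are of whole genes.

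How many genes were called rested on single libraries. Without 2D replicate 2, the test called 3473 genes higher and 4192 lower, the 6 among them, and without any one of the other 5 libraries it called 0 (2004 to 3228 genes at an unadjusted p under 0.05). Leaving out 2D replicate 2 makes culture coincide with the GC-linked division of the libraries. Neither these calls nor later values without that library can tell culture from that division. With all 6 libraries DESeq2 called 846 higher and 1976 lower, and edgeR with a correction for GC content and transcript length, added after the data were seen, called 486 higher and 381 lower. All 6 genes were among the calls of both, and limma-voom called these 6 alone. The GC and length correction was fitted without regard to culture. It therefore also takes out any real difference between the cultures that follows GC content or length, here and in all values below.

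**Figure D2:**
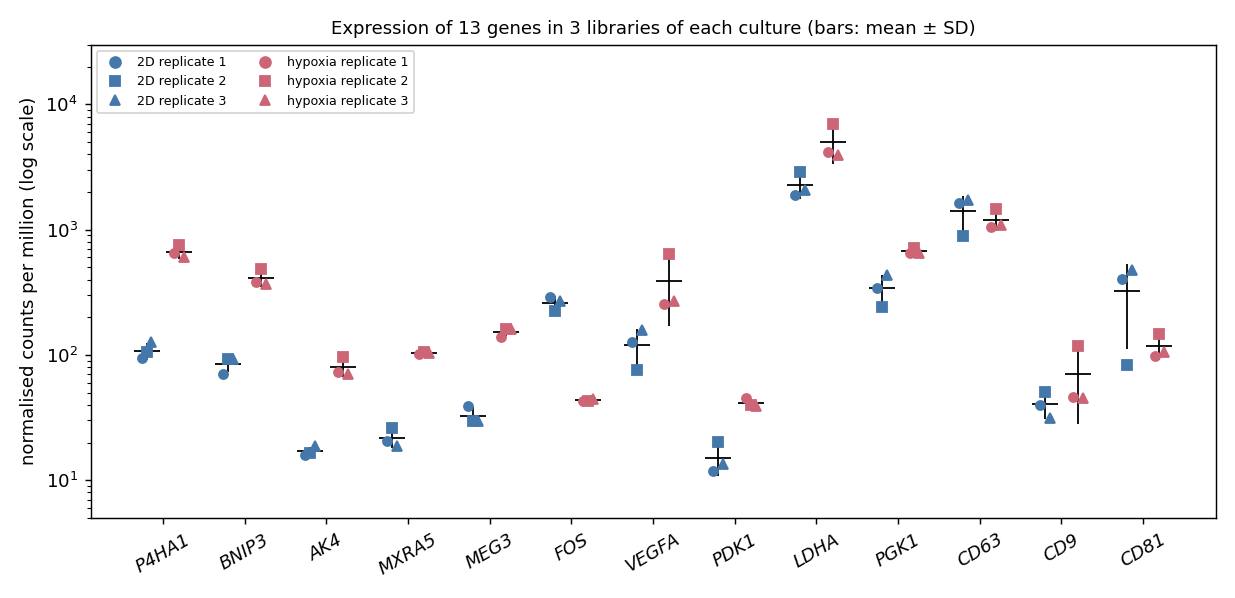
CPM (vertical axis, log scale) of 13 genes (horizontal axis) in the 3 libraries of 2D and the 3 of hypoxia, with color for culture, marker shape for replicate and black bars for the mean ± SD. The libraries of the 2 cultures do not overlap for P4HA1, BNIP3, AK4, MXRA5, MEG3 and FOS, whereas for CD63 and CD9 they do.

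Genes known to be induced by low oxygen were higher as a group in hypoxia. The median log2 fold change of the 30 tested members of the hypoxia response list was 1.07, and 24 had a higher mean, 20 of them with every hypoxia library above every 2D library. Exchangeable libraries would give 10% of genes without overlap, counting both directions, but these were not exchangeable. Of 50 tested EV genes, a list that was not called, 3 lay above and 17 below without overlap. The share over all tested genes is not given here. P4HA1, BNIP3 and AK4 rose, and 19 members were higher and 1 lower when adjusted over the list alone. VEGFA, the main angiogenic growth factor, had means of 120 ± 41.6 and 387 ± 217 CPM (log2 fold change 1.68 ± 0.45, edgeR adjusted p = 0.110), and CA9, a carbonic anhydrase, 0.702 ± 0.368 and 3.13 ± 2.95 CPM (2.15 ± 0.75, adjusted p = 0.124). CA9 had 6.52 CPM in hypoxia replicate 2, and its log2 fold change without that library was 1.011. EGLN1, the oxygen-sensing hydroxylase that marks HIF-1 alpha for destruction, had a log2 fold change of 1.15 ± 0.17 (adjusted p = 0.104). The HIF subunits themselves showed no detectable change, with -0.26 ± 0.39 for HIF1A (adjusted p = 0.678) and -0.40 ± 0.25 for EPAS1 (adjusted p = 0.311). The sign of HIF1A turned without 2D replicate 2 (0.11) or hypoxia replicate 2 (0.04). Camera with a preset correlation gave the list an adjusted p of 2.08e-08 over 31 lists (adjusted p = 0.462 with an estimated correlation). The 7 members of the list of oxygen sensors and HIF subunits had a median of -0.26 (adjusted p = 0.835, 1 member higher adjusted over the list alone, EGLN1). The hypoxia response median stayed between 0.91 and 1.18 in all 19 alternatives, among them 1.15 with 2D replicate 2 as the only 2D library.

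Glycolytic genes were divided. Of 24 tested genes of glycolysis and glucose uptake 12 had a higher and 12 a lower mean. In edgeR 0 passed over all genes (7 higher and 2 lower at an unadjusted p under 0.05, and 6 higher and 1 lower in DESeq2), and 3 were higher when adjusted over the list alone. Those were PDK1, the kinase that keeps pyruvate out of the mitochondrion (15.1 ± 4.37 and 41.5 ± 3.39 CPM, log2 fold change 1.46 ± 0.26), PGK1, a glycolytic enzyme (340 ± 99.0 and 670 ± 34.1 CPM, 0.98 ± 0.25), and LDHA, which makes lactate (2274 ± 518 and 5036 ± 1683 CPM, 1.15 ± 0.29), each at an edgeR adjusted p of 0.110. SLC2A1, the glucose transporter GLUT1, had 0.92 ± 0.43 (adjusted p = 0.1997), and 0.51 without hypoxia replicate 2. The list's median was 0.04 (camera adjusted p = 0.156), turned to -0.02 with library totals and to -0.17 without 2D replicate 2, and was 0.29 (adjusted p = 0.00298) without 2D replicate 3 (all 6 libraries, adjusted p = 0.681 with an estimated correlation). With the GC and length correction it was 0.49 with 8 members higher (adjusted p = 6.86e-06, and 0.371 with an estimated correlation). The list's median was 0.46 with 1 surrogate variable (camera adjusted p = 1.29e-05) and 0.79 with 2D replicate 2 as the only 2D library.

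Enzymes of the TCA cycle and fatty acid oxidation were lower as a group. More subunits of oxidative phosphorylation were lower than higher, with a call that rested on single libraries. Of 30 tested genes of the TCA cycle and fatty acid oxidation 28 had a lower mean in hypoxia and the median was -0.47. In edgeR 0 passed over all genes (13 lower at an unadjusted p under 0.05, and 9 in DESeq2) and 8 were lower when adjusted over the list alone, such as IDH3B (log2 fold change -1.12 ± 0.24) and OGDH (-1.14 ± 0.30), both TCA cycle dehydrogenase subunits, each at an edgeR adjusted p of 0.110. With the GC and length correction these values were -0.61 and -0.57. Camera gave an adjusted p of 6.33e-04 (adjusted p = 0.462 with an estimated correlation). The 67 tested nuclear-encoded subunits of oxidative phosphorylation had a lower mean in 42 and a higher one in 25, and a median of -0.22 (camera adjusted p = 0.0377, and adjusted p = 0.667 with an estimated correlation), with 0 members past edgeR's threshold over all genes or over the list alone (25 lower and 1 higher at an unadjusted p under 0.05, and 22 lower and 1 higher in DESeq2). That call ended without 2D replicate 2 (median -0.29, adjusted p = 0.121), hypoxia replicate 1 (-0.13, 0.130) or hypoxia replicate 3 (-0.15, 0.135). It also ended with the replicate block (-0.20, camera adjusted p = 0.101). The call held with the GC and length correction (-0.22, camera adjusted p = 0.00765) and with 1 surrogate variable (-0.16, adjusted p = 0.0104). The 3 members with the smallest p went both ways. COX8A, a cytochrome oxidase subunit, had 89.2 ± 65.2 CPM in 2D and 12.45 ± 1.61 in hypoxia (log2 fold change -2.84 ± 0.71), and CYC1, cytochrome c1, 69.7 ± 37.0 and 20.5 ± 1.17 (-1.77 ± 0.44), each at an edgeR adjusted p of 0.110. Both were smaller with the GC and length correction (-1.81 and -0.48) and against 2D replicate 2 alone (-0.37 and -0.42). NDUFA4L2, a paralog of a cytochrome oxidase subunit, had 1.49 ± 1.30 CPM in 2D and 10.5 ± 1.67 in hypoxia (log2 fold change 2.77 ± 0.69, edgeR adjusted p = 0.110).

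Fibrillar collagen and matrix genes were higher as a list in the main test, while collagen-modifying enzymes and matrix proteases were not called as lists. In the list of fibrillar collagens and other extracellular matrix, 19 of 25 tested genes had a higher mean and the median was 0.46. In edgeR 0 passed over all genes (10 higher and 2 lower at an unadjusted p under 0.05, and 8 higher and 1 lower in DESeq2), and 7 were higher and 1 lower when adjusted over the list alone. COL3A1, the chain of type III collagen, had 5876 ± 590 CPM in 2D and 11610 ± 1720 in hypoxia (log2 fold change 0.98 ± 0.19), VCAN, a large proteoglycan, 1474 ± 446 and 4051 ± 755 (1.46 ± 0.28), and THBS2, a matricellular protein, 1025 ± 150 and 2204 ± 83.3 (1.10 ± 0.19), each at an edgeR adjusted p of 0.110. Camera gave an adjusted p of 0.00335 (adjusted p = 0.462 with an estimated correlation, and 0.121 without 2D replicate 2, where the median was 0.50). Among 18 tested collagen-modifying enzymes P4HA1 rose, and 3 were higher when adjusted over the list alone: P4HA1, PLOD2, a lysyl hydroxylase (932 ± 163 and 3270 ± 457 CPM, 1.81 ± 0.22, edgeR adjusted p = 0.0810), and LOX, which crosslinks collagen (1.22 ± 0.29, adjusted p = 0.110). The whole list had a median of 0.05 (camera adjusted p = 0.202), which turned to -0.01 with library totals and to -0.27 without 2D replicate 2, and was called without 2D replicate 3 (0.34, adjusted p = 0.00901) and with the GC and length correction (0.76, adjusted p = 5.51e-06, and 0.328 with an estimated correlation). It was also called with 1 surrogate variable (0.74, camera adjusted p = 1.77e-05), and its median was 0.94 with 2D replicate 2 as the only 2D library. Matrix proteases and their inhibitors (19 genes) had a median of 0.02, or -0.07 with library totals (camera adjusted p = 0.302), with SERPINE2, a serine protease inhibitor (1.29 ± 0.23), among 3 members higher and ADAMTS5, an aggrecanase (-1.17 ± 0.31), the 1 lower when adjusted over the list alone (both edgeR adjusted p = 0.110). That list's median was 0.62 with the GC and length correction (adjusted p = 0.0611). With 2D replicate 2 as the only 2D library it was 0.45 (adjusted p = 0.0401, against adjusted p = 0.667 with an estimated correlation on all 6).

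Cell cycle genes were lower in hypoxia. Of 39 tested proliferation genes 37 had a lower mean, 28 of them with every hypoxia library below every 2D library, and the median was -0.70. Lack of overlap in that direction was also seen in 27 of 56 cytosolic ribosomal protein genes. Over all genes 0 passed in edgeR (23 lower at an unadjusted p under 0.05, and 19 in DESeq2) and 20 were lower when adjusted over the list alone. FOXM1, a transcription factor of the G2 and M phases, had 39.9 ± 11.1 CPM in 2D and 12.2 ± 1.39 in hypoxia (log2 fold change -1.71 ± 0.27), BIRC5, the mitotic protein survivin, 56.1 ± 19.3 and 17.2 ± 2.60 (-1.71 ± 0.31), and CDC20, an activator of the anaphase-promoting complex, 34.9 ± 10.5 and 11.4 ± 1.15 (-1.62 ± 0.28), each at an edgeR adjusted p of 0.110. Camera gave an adjusted p of 2.99e-09 (adjusted p = 0.462 with an estimated correlation). Against 2D replicate 2 alone the list's median was -0.84, and FOXM1, BIRC5 and CDC20 had -1.135, -0.973 and -1.001.

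Immediate-early genes, transcribed within minutes of a stimulus, were lower too. Of 17 tested, 16 had a lower mean, FOS fell, and the median was -1.41. Adjusted over the list alone 14 were lower, such as EGR1 (342 ± 149 and 115 ± 22.7 CPM, log2 fold change -1.58 ± 0.36, edgeR adjusted p = 0.110), and EGR2, named after its value was seen, was higher (1.87 ± 0.44, adjusted p = 0.110). Camera gave an adjusted p of 1.24e-05 (adjusted p = 0.616 with an estimated correlation). The median of the list was -0.73 in 2D replicate 2 relative to the 2D mean, against 0.33 and 0.31 in 2D replicates 1 and 3, and -0.35 (camera adjusted p = 5.75e-04) when hypoxia was set against 2D replicate 2 alone, where EGR1 had -0.73.

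Antioxidant and sterol genes were lower. Targets of NRF2, the transcription factor of the oxidative stress response, had a lower mean in 16 of 21 tested genes and a median of -0.99. In edgeR 0 passed over all genes (11 lower at an unadjusted p under 0.05, and 10 in DESeq2) and 10 were lower when adjusted over the list alone. NQO1, a quinone reductase, had 407 ± 248 CPM in 2D and 73.0 ± 29.3 in hypoxia (log2 fold change -2.48 ± 0.54), and PGD, of the pentose phosphate pathway, 132 ± 51.1 and 47.3 ± 3.98 (-1.48 ± 0.31), each at an edgeR adjusted p of 0.110. Camera gave an adjusted p of 0.00195 (adjusted p = 0.616 with an estimated correlation). The median was -0.29 with 2D replicate 2 as the only 2D library, where NQO1 had -1.185 and PGD -0.75. In cholesterol biosynthesis 17 of 23 genes had a lower mean and the median was -0.64 (camera adjusted p = 0.0140, and adjusted p = 0.616 with an estimated correlation), with 0 members past edgeR's threshold over all genes (10 lower and 1 higher at an unadjusted p under 0.05, and 8 lower in DESeq2). Adjusted over the list alone 8 were lower, such as MVK, mevalonate kinase (-2.16 ± 0.48, edgeR adjusted p = 0.110). That call ended without 2D replicate 2 (median -0.77, adjusted p = 0.121) or hypoxia replicate 2 (-0.57, adjusted p = 0.0813), and the median was -0.37 with the GC and length correction. The 5 tested metallothioneins, small metal-binding proteins, had a median of -1.12 (camera adjusted p = 0.0309, and adjusted p = 0.616 with an estimated correlation), with 0 members past edgeR's threshold over all genes or the list alone (3 lower at an unadjusted p under 0.05, and 0 in DESeq2). This call ended without 2D replicate 2 (median -1.38, adjusted p = 0.175), without hypoxia replicate 3 (-0.92, adjusted p = 0.0602) and with the GC and length correction (-0.30, adjusted p = 0.359). It also ended with the replicate block (-1.205, camera adjusted p = 0.0580) and with 1 surrogate variable (-0.45, adjusted p = 0.122). Against 2D replicate 2 alone the metallothionein median was -0.24.

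**Figure D3:**
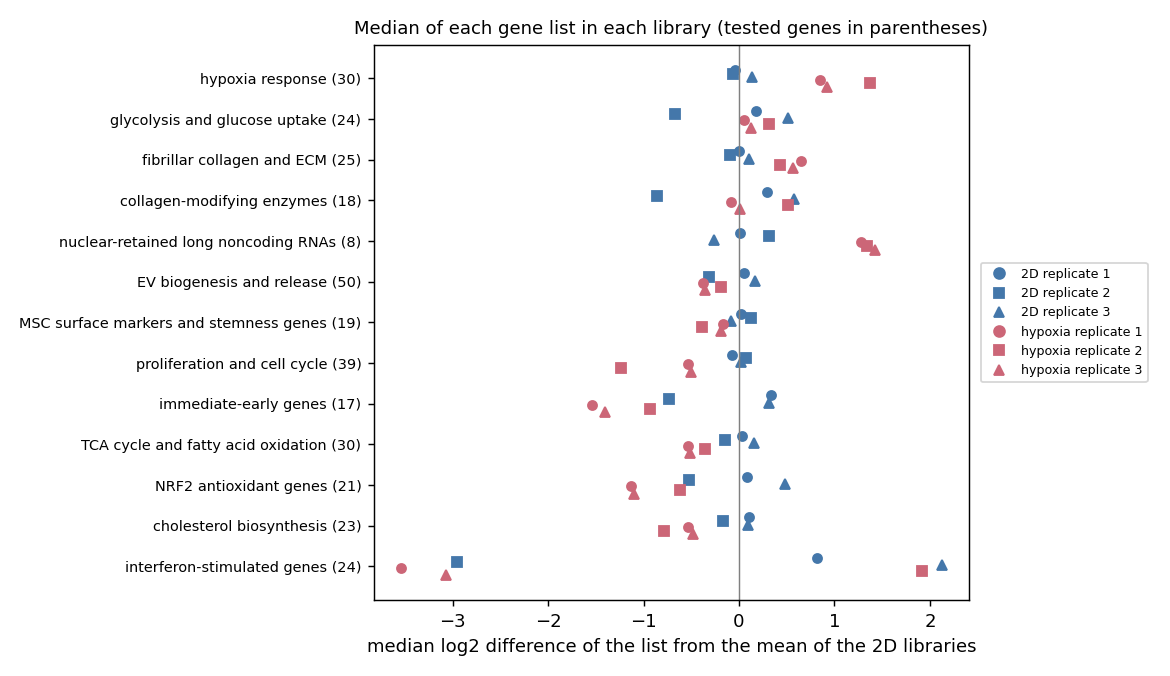
Median over the tested members of 13 gene lists (vertical axis, number of genes in parentheses) of the log2 difference of each library from the mean of the 2D libraries (horizontal axis), with color for culture and marker shape for replicate. The 3 hypoxia libraries lie at 0.85 to 1.37 for the hypoxia response and at -1.23 to -0.50 for proliferation, apart from the 2D libraries, while for the interferon-stimulated genes 2D replicate 2 (-2.95) lies with hypoxia replicates 1 and 3, and hypoxia replicate 2 (1.92) with 2D replicate 3.

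Genes that make and release EVs did not pass as a group. Of 50 tested members 21 had a higher and 29 a lower mean, and the median was -0.27 (camera adjusted p = 0.121, and 0.616 with an estimated correlation). In edgeR 0 passed over all genes or over the list alone, beside 21 lower at an unadjusted p under 0.05 and 15 lower in DESeq2. Of the tetraspanins used as EV markers, CD63 had 1416 ± 455 CPM in 2D and 1199 ± 222 in hypoxia (log2 fold change -0.24 ± 0.29), CD9 40.7 ± 9.63 and 70.2 ± 42.0 (0.79 ± 0.42), and CD81 322 ± 210 and 117 ± 26.1 (-1.46 ± 0.59), with edgeR adjusted p of 0.602, 0.247 and 0.152. TSG101 of the ESCRT-I complex had a log2 fold change of 0.08 ± 0.18 (adjusted p = 0.783), and PDCD6IP, the ESCRT-associated protein ALIX, 0.54 ± 0.23 (adjusted p = 0.168). The 3 members with the smallest p were lower in hypoxia: MVB12A, an ESCRT-I subunit (27.1 ± 17.15 and 5.36 ± 0.765 CPM, log2 fold change -2.35 ± 0.58), CHMP6, an ESCRT-III subunit (-1.91 ± 0.44), and FLOT2, a flotillin (49.4 ± 20.98 and 18.5 ± 1.80 CPM, -1.42 ± 0.36), each at an adjusted p of 0.110. HGS, an ESCRT-0 subunit, had -1.34 ± 0.44 (adjusted p = 0.115). These differences shrank with the GC and length correction, to -1.25 for MVB12A (adjusted p = 0.0436), -0.39 for CHMP6, -0.60 for FLOT2 (adjusted p = 0.0362) and 0.03 for HGS, while CD81 turned to 0.04 and CD63 to 0.27. Against 2D replicate 2 alone CD81 had 0.50 and CD63 0.44, and without hypoxia replicate 2 CD9 had 0.18. For the RAB GTPases that dock vesicle-bearing endosomes the values were 0.18 ± 0.32 for RAB27A (adjusted p = 0.729) and -0.98 ± 0.37 for RAB27B (adjusted p = 0.139). Without 2D replicate 2 RAB27A had 0.57 (adjusted p = 0.0411), and against that library alone -0.36. SMPD3, which encodes a neutral sphingomyelinase, had 5, 3 and 12 counts in 2D and 11, 8 and 6 in hypoxia, too few to be tested. With the GC and length correction the list's median was -0.04 and 5 members were lower, and with 2D replicate 2 as the only 2D library it was -0.11 (camera adjusted p = 0.0375).

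Surface markers that define hMSCs did not move together. The 19 tested surface markers and stemness genes had a median of -0.47 (camera adjusted p = 0.276, while fry called the list lower at an adjusted p of 0.0218). Over all genes 0 passed in edgeR (1 higher and 3 lower at an unadjusted p under 0.05, and the same numbers in DESeq2) and 1 was lower when adjusted over the list alone, KLF4 (48.2 ± 13.3 and 15.5 ± 1.06 CPM, log2 fold change -1.64 ± 0.26, edgeR adjusted p = 0.110). The defining markers had log2 fold changes of 0.55 ± 0.28 for NT5E (CD73, adjusted p = 0.224), -0.70 ± 0.37 for THY1 (CD90, adjusted p = 0.247) and -1.02 ± 0.44 for ENG (CD105, adjusted p = 0.174). With the GC and length correction the list's median was 0.0126 (camera adjusted p = 0.700), THY1 had 0.01 and ENG turned to 0.33. Without hypoxia replicate 2 the list's median was -0.18 and NT5E had 0.24. The differentiation lists were not called either, at medians of 0.09 for 9 osteogenic genes (camera adjusted p = 0.547), -0.43 for 7 adipogenic genes (0.276) and 0.46 for 9 chondrogenic genes (0.302). Against 2D replicate 2 alone the adipogenic median turned to 0.36, and without hypoxia replicate 3 the chondrogenic one was 0.13. Among chondrogenic genes HAPLN1, a cartilage link protein, had 307 ± 232 and 1786 ± 1605 CPM and ACAN, aggrecan, 148 ± 54.8 and 22.7 ± 18.7, with edgeR adjusted p of 0.111 and 0.138. Hypoxia replicate 2 had 3639 CPM of HAPLN1, whose log2 fold change was 1.49 without it and 2.54 with it. Contractile and TGF-beta genes (20 tested) had a median of 0.19 and a mean of the opposite sign, -0.00211, with camera's direction upward (adjusted p = 0.480). TAGLN, a smooth muscle actin-binding protein, had 4619 ± 2548 and 1620 ± 148 CPM (-1.51 ± 0.46, edgeR adjusted p = 0.110), with 1703 CPM in 2D replicate 2. Its log2 fold change was -0.05 against that library alone and -0.73 with the GC and length correction.

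Secreted factors and stress responses gave 1 call. Inflammatory and immunomodulatory factors had a higher mean in 21 of 26 genes and a median of 0.81 (camera adjusted p = 0.0309, and adjusted p = 0.667 with an estimated correlation). Relative to the 2D mean, their median was lowest in hypoxia replicate 1 (-0.446), against 1.355 and 0.631 in hypoxia replicates 2 and 3. In 2D replicates 1 to 3 it was 0.0399, -0.192 and 0.145. In edgeR 0 members passed over all genes or the list alone (8 higher and 1 lower at an unadjusted p under 0.05, and 7 higher and 1 lower in DESeq2). The call ended without 2D replicate 2 (median 0.86, adjusted p = 0.304) and with the GC and length correction (0.82, adjusted p = 0.0611), where the median stayed as large. It also ended without hypoxia replicate 2, where the median was smaller (0.34, adjusted p = 0.310). CD274, the checkpoint ligand PD-L1, had 4.53 ± 1.19 CPM in 2D and 12.5 ± 6.14 in hypoxia (log2 fold change 1.47 ± 0.41, edgeR adjusted p = 0.110). Angiogenic and trophic factors (33 genes) had a median of -0.000414, below 0, while their mean (0.0398) and camera's direction were above it (adjusted p = 0.478). DESeq2 size factors turned the median to 0.0105. Among them VEGFA and STC1, the hormone stanniocalcin 1 (log2 fold change 1.65 ± 0.42, edgeR adjusted p = 0.110), had higher means. The p53 and senescence list (21 genes) had a median of 0.54 (camera adjusted p = 0.0786). It was called without 2D replicate 1 (adjusted p = 0.0314), 2D replicate 3 (0.0262), hypoxia replicate 1 (0.0154) or hypoxia replicate 3 (0.0387) and with the GC and length correction (8.42e-04). The last call was lost with an estimated correlation (adjusted p = 0.371), where all 6 libraries uncorrected had an adjusted p of 0.667. Without hypoxia replicate 2 the list's median was 0.10 (adjusted p = 0.373), and without 2D replicate 2 it was 0.45 (adjusted p = 0.458). The cyclin-dependent kinase inhibitor CDKN2B had 61.1 ± 39.2 and 271 ± 87.1 CPM (2.15 ± 0.55, edgeR adjusted p = 0.110). Unfolded protein and amino-acid stress genes (22) had a median of 0.21 and a mean of 0.0153 (camera adjusted p = 0.228). Adjusted over the list alone, 6 were higher and 2 lower, such as the endoplasmic reticulum chaperones HSP90B1 (1.36 ± 0.23) and HSPA5 (1.19 ± 0.32), both at an edgeR adjusted p of 0.110. That list was called without 2D replicate 3 (adjusted p = 0.0427) and with the GC and length correction (0.00281, and adjusted p = 0.540 with an estimated correlation). It was also called with 1 surrogate variable (median 0.69, camera adjusted p = 2.73e-04), and its median was 0.77 with 2D replicate 2 as the only 2D library. Without 2D replicate 2 its median was 0.0123 (adjusted p = 0.826), and without hypoxia replicate 2 it was 0.03 (adjusted p = 0.569), where HSPA5 had 0.76. Lysosome and autophagy genes (29) had a median of -0.52 (camera adjusted p = 0.144), called without hypoxia replicate 2 (-0.66, adjusted p = 0.0342, against adjusted p = 0.681 with an estimated correlation on all 6), and 0.02 with the GC and length correction.

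Interferon-stimulated genes differed more within each culture than between them. Their 24 tested members had a median log2 fold change of -0.84 (camera adjusted p = 0.0786), and without hypoxia replicate 2 it was -4.59 (adjusted p = 3.82e-06, against adjusted p = 0.681 with an estimated correlation on all 6 libraries). With 1 surrogate variable or with 2D replicate 2 as the only 2D library its sign turned (1.52 and 3.24), as it did without 2D replicate 3 (0.26), each time without a call. ISG15, a ubiquitin-like protein induced by interferon, stood at 365, 5.15 and 971 CPM in 2D replicates 1 to 3 and at 4.02, 175 and 4.48 CPM in hypoxia replicates 1 to 3 (-2.87 ± 1.92, edgeR adjusted p = 0.342). In edgeR 0 members passed over all genes or over the list alone, with 0 at an unadjusted p under 0.05 and 0 in DESeq2.

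Markers of blood cells were low, whereas some keratins were not. The most abundant hematopoietic marker tested was CD74, at 22.3 ± 16.9 CPM in 2D and 3.75 ± 2.31 in hypoxia (log2 fold change -0.61 against 2D replicate 2 alone), and the 6 tested had a median of -0.997 (camera adjusted p = 0.247). The most abundant of 5 tested endothelial markers was TEK (42.0 ± 16.6 and 57.4 ± 29.01 CPM), with a list median of -0.42 (camera adjusted p = 0.494). That median was -0.02 without hypoxia replicate 2 (adjusted p = 0.971) and 0.07 without 2D replicate 2 (adjusted p = 0.734). Of 8 epithelial markers, all with a lower mean in hypoxia, KRT18, a keratin that stromal cells in culture also express, was the most abundant (314 ± 86.6 and 242 ± 21.5 CPM). Their median was -0.65 (camera adjusted p = 0.0309, and adjusted p = 0.462 with an estimated correlation). Over all genes 0 passed in edgeR (3 lower at an unadjusted p under 0.05, and 2 in DESeq2) and 2 were lower when adjusted over the list alone, CLDN4 (1.82 ± 0.722 and 0.277 ± 0.0990 CPM) among them. The call ended, with a smaller median, without 2D replicate 2 (-0.27, adjusted p = 0.249), without hypoxia replicate 3 (-0.42, adjusted p = 0.0920) and with the GC and length correction (-0.33, adjusted p = 0.189).

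RNA classes that can follow RNA quality also moved with the groups. The list of nuclear-retained long noncoding RNAs (8 tested) had a median of 1.35 (camera adjusted p = 2.28e-04, and adjusted p = 0.462 with an estimated correlation). It also holds the small nucleolar RNA host genes GAS5, SNHG1 and SNHG5, so it is not purely nuclear. MEG3 rose, and 6 were higher when adjusted over the list alone, while MALAT1, a nuclear speckle RNA and the most abundant, had 279 ± 182 and 564 ± 179 CPM (1.02 ± 0.47, edgeR adjusted p = 0.197). MALAT1 had 1.696 without 2D replicate 2 (adjusted p = 0.00437) and 0.23 against that library alone. Cytosolic ribosomal protein genes (56) had a median of -0.33 (camera adjusted p = 0.00195, and adjusted p = 0.462 with an estimated correlation), with 0 past edgeR's threshold over all genes or the list alone, 23 lower at an unadjusted p under 0.05 and 18 lower in DESeq2. Their median was -0.21 with the GC and length correction (camera adjusted p = 0.00638) and -0.19 with 2D replicate 2 as the only 2D library. Replication-dependent histone genes (7) had a median of 0.36 (camera adjusted p = 0.0786) and were called without 2D replicate 3 (adjusted p = 0.00577), hypoxia replicate 1 (0.0154) or hypoxia replicate 3 (0.0349), against an adjusted p of 0.667 with an estimated correlation on all 6. Without hypoxia replicate 2 their median was 0.06 (adjusted p = 0.310), without 2D replicate 2 it was 0.23 (adjusted p = 0.579), and with the GC and length correction 0.77 (adjusted p = 0.0611). With library totals the histone list was called (0.30, adjusted p = 0.0455), and without a low-count filter its median was 0.04. Of the 13 lists called, 7 were called whichever single library was left out: the hypoxia response, proliferation, immediate-early, nuclear long noncoding, TCA cycle and fatty acid oxidation, NRF2 and ribosomal protein lists. Leaving out a library does not test the preset correlation of 0.01. The estimated correlations of these 7 lists were 0.0515 to 0.566. With an estimated correlation 0 of the 31 lists were called, and fry, which tests whether a list moves one way on balance, called 7.

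The authors' deposited table of the same comparison lists 16026 genes, of which 3997 had an adjusted p under 0.05, 1447 higher and 2550 lower in hypoxia. Its log2 fold changes correlated with those from edgeR across the 10872 genes present in both (Pearson's r = 0.999, over genes, which are not independent replicates), and 95.1% had the same sign. The 6 genes called in edgeR were called in the same direction in the authors' deposited table, where P4HA1 had a log2 fold change of 2.71 and FOS one of -2.40. DESeq2 run on the counts shared 2468 calls with it. For 2741 (74.6%) of the 3673 genes called in the authors' deposited table and tested here, 2D replicate 2 lay nearer to the hypoxia mean than to 2D replicates 1 and 3. The genes it called higher had a median transcript GC content of 43.5% and those it called lower 59.9%.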

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

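Reads that fell in no gene, which enter no comparison above, were more frequent in hypoxia, at 8.32%, 7.65% and 8.60% of the total in hypoxia replicates 1 to 3 against 3.40%, 5.08% and 2.80% in 2D replicates 1 to 3. The means were 8.19 ± 0.488% and 3.76 ± 1.18% (SD, n = 3 each, two-sided exact permutation test p = 0.1, the smallest that 3 against 3 allows). Both tests of this pattern were chosen after these shares had been seen and before their own results were, except the interval between libraries of the first, chosen after its ratio was seen. Genomic DNA would raise reads over silent genes alike. The summed level of 401 olfactory receptor genes was 1.02 times as high in hypoxia as in 2D (95% interval from the spread between libraries 0.446 to 2.35, quasi-Poisson). With 4 to 29 such reads per library this leaves genomic DNA open. Unspliced RNA remains open too: 82 noncoding genes lying inside tested protein-coding genes had a median log2 fold change of 0.48 and 188 outside any gene 0.16, a difference of 0.319 (0.0637 to 0.680) that fell short of the 0.5 set beforehand, so genomic DNA, more unspliced RNA and a change of transcription in hypoxia cannot be told apart here, and a response to low oxygen itself was not tested.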

How the results depend on the processing

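The counts of called genes moved with the libraries and the test. From 5 higher and 1 lower, leaving out a library gave 0 to 3473 higher and 0 to 4192 lower, DESeq2 gave 846 and 1976, the GC and length correction 486 and 381, 1 surrogate variable 13 and 2, no filter 10 higher, and an adjusted p under 0.01 gave 0 and 0. With 2D replicate 2 as the only 2D library the counts were 0 and 0 (1297 genes at an unadjusted p under 0.05). Both fits with a replicate block, without and with the GC and length correction, gave 0 and 0 (2364 and 3747 genes at an unadjusted p under 0.05). Libraries with the same replicate number did not deviate together (correlations across genes of -0.196, -0.244 and -0.145). The 2D deviations include the GC-linked division of 2D replicate 2, which could hide a pairing, so these values cannot exclude one. The other scalings, limma-voom, the stricter filter and both fold thresholds stayed within 1.5 times of the main counts. The hypoxia response list kept its call except with an estimated correlation (1.07, adjusted p = 0.462). The EV list was called only with 2D replicate 2 as the lone 2D library (-0.11, adjusted p = 0.0375, over a range of 0.0375 to 0.616). Calls shared with the authors' deposited table were 6 in edgeR, 2468 in DESeq2 and 562 with the GC and length correction. Only 10872 of the 13918 tested genes had an entry in that table, so calls on the rest could not be shared. Over the alternatives, lists kept the direction of their test and the side of the threshold in 502 cases, gained a call in 32, lost it in 42 and changed direction without a call in 11, and for the 98 named genes, by the sign of the fold change, these numbers were 1418, 161, 43 and 41. The median of the interferon-stimulated genes ranged from -4.59 to 3.24. 0 called values reversed. The correction, surrogate variable, lone-library fit and their counts were chosen after the data were seen. Apart from the smaller number of samples where libraries were left out, the cause of these changes was not tested.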

Other observations

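With GC content and length corrected, a fit chosen after the data were seen, edgeR called 867 genes, of which 824 had the same sign as without the correction. Camera then called 14 lists, and 0 with an estimated correlation. Examples, chosen after their values were seen, were NDUFA4L2 (log2 fold change 4.31 ± 0.35, adjusted p = 0.0125), the transcribed pseudogene FER1L4 (4.203 ± 0.30, adjusted p = 0.0125), PFKFB3, which makes the activator of glycolytic phosphofructokinase (1.46 ± 0.19, adjusted p = 0.0257), the glycolytic enzyme TPI1 (0.98 ± 0.12, adjusted p = 0.0257), OGT, the enzyme that attaches O-GlcNAc (1.11 ± 0.09, adjusted p = 0.0125), and the collagen chain COL5A1 (1.21 ± 0.12, adjusted p = 0.0157), all higher. RBM3, a cold-inducible RNA-binding protein, was lower (-1.77 ± 0.19, adjusted p = 0.0217). Without the correction the same genes had log2 fold changes of 2.77, 3.15, 1.00, 0.19, 1.42, 0.28 and -1.68 with edgeR adjusted p of 0.0949 to 0.741. Among the 437 tested genes named as ZNF zinc fingers, a family noticed in the results, 37 were called higher and 1 lower with the correction. Over all 13918 tested genes it was 486 higher and 381 lower. The family was picked from these same calls and was not tested as a group.

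The median log2 fold change of long noncoding RNAs was 0.22 over 618 genes and that of pseudogenes 0.47 over 220, against -0.05 over 12706 protein-coding genes, and 0.31, 0.53 and -0.02 with the GC and length correction. These classes were not tested as groups. Hypoxia replicate 2 was the highest hypoxia library in 27 of 30 hypoxia response genes, 18 of 24 glycolysis genes, 17 of 33 angiogenic and trophic factors and 2 of 39 proliferation genes, against 46.2% of all tested genes.

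The first pattern weighed is the place of 2D replicate 2 beside the hypoxia libraries (position 0.840). The test of a wrong label was chosen after the result was seen, the others before. A hypoxia library under a 2D label would carry the induced genes, yet over the 15 hypoxia response genes at least 1 log2 unit above 2D replicates 1 and 3 its median position was 0.0825 (-0.0213 to 0.350), below 0.5 in 14 of them. Lower depth as the cause is argued against by thinning to equal depth, which left the position at 0.843 (0.833 to 0.855). Correction for GC content and length moved it to 0.586 (0.564 to 0.605), above the 0.5 set beforehand. That value cannot decide whether this bias was the whole cause, since spread in the mean of 2D replicates 1 and 3 alone raises the position. A hypothesis is that a difference in RNA or library preparation linked to base composition may account for part or all of the likeness. Whether anything else adds to it, including a difference in the state of that culture, stays open and untested.

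The second pattern is the division of the libraries by interferon-stimulated genes, for which the exchange of labels was tested only after the result was seen. Beside ISG15, MX1, named after its values were seen, stood at 460, 14.3 and 1186 CPM in 2D replicates 1 to 3 and at 5.11, 919 and 6.27 CPM in hypoxia replicates 1 to 3, and the library medians of the 24 genes spanned 5.59 log2 units. Bias of GC content and length is argued against by a span of 5.35 (4.12 to 6.08) after correction. An exchange of 2D replicate 2 with hypoxia replicate 2 would leave the latter without induced hypoxia genes, but its median position over 13 of them was 1.199 (1.13 to 1.29), with 0 for 2D replicates 1 and 3 and 1 for hypoxia replicates 1 and 3. That some cultures were exposed to an interferon stimulus may be considered, as a hypothesis with no group in the labels to test it.

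Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The split of the gene count was chosen after the result was seen, those of the lists before. As many called genes as in the real split (6) were found in 2 of the 10, the real one included. The highest other split called 31 genes, several times the real count, and it set 2D replicates 1 and 3 with hypoxia replicate 2 against the rest. It thus follows a structure of the samples, since 16 of the 31 were among the 24 interferon-stimulated genes. With the GC and length correction the real split called 867 and the highest other 35. For the hypoxia response list 3 of the 10 splits had a camera p as small (1.34e-09 in the real split, 7.09e-14 as the smallest other), and for the EV list 3 of the 10 (0.0664 and 0.0439). Splits that mixed the cultures thus gave the hypoxia response list a smaller camera p than culture did. The other lists were not split in this way, so their camera p-values were not checked against mixed splits.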
